A study of Mus musculus with 4 samples.

How the data were processed

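RNA sequencing was done on C22 cells, an immortalized mouse line of Club cells, the secretory cells of the small airways. Per the labels' protocols, cells received norepinephrine at 10 µM or vehicle for 3 h, total RNA was extracted with an RNeasy kit, libraries were made with the NEBNext Ultra II RNA kit and sequenced on a NovaSeq X instrument. The series holds 4 libraries, 2 per group, and the group of each was taken from its title. Matching between the columns of the deposited table and the samples followed the library descriptions in the labels.

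The deposited values are raw read counts per gene, per the labels and the column names, as whole numbers with a different total in each library. The genome build is GRCm39 (mm39), per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of a partner on the opposite strand cannot be told apart, and reads of genes whose exons overlap or of near-identical copies can be split between identifiers by the counting. The values of such genes are uncertain.

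The table lists 22063 gene identifiers, of which 7127 had 0 counts in all 4 libraries. Gene symbols came from the deposited table itself. No symbol stood beside 30 identifiers, which held 0.000742% of the counts, and 20 symbols stood beside more than 1 identifier. Total counts ranged from 14783176 to 18491334 per library. In a single library 3 counts, the upper limit that a count of 0 allows, correspond to between 0.162 and 0.203 CPM (counts scaled to a common library total), and to 0.0471 CPM over the 4 libraries together. These limits cover counting error only, since reads without molecular identifiers are not independent molecules.

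The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15) and libraries were scaled by TMM. NE was compared with vehicle by the quasi-likelihood test, with group as the model's only term. Adjusted p-values are Benjamini-Hochberg values over the 11419 genes kept, and a gene is called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes are the absolute fold change divided by the square root of the F statistic, and 95% intervals use the t distribution with the moderated degrees of freedom. CPM values are given as group mean ± SD over 2 libraries and use the TMM-scaled totals of the genes kept. The CPM limits for a count of 0 use the total counts.

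Before the data were examined, 42 gene lists were fixed: responses to cAMP, calcium, growth factor, inflammatory and stress signals, metabolism, cell cycle, adipose-linked secreted factors, and markers of lung cell types. The symbol was found for 974 of their 986 entries. The 35 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. This tests each list against the other genes, with Benjamini-Hochberg adjustment over the 35 lists. The same test with an estimated correlation, and fry, were run beside it. Whether these can call a changed list with 2 libraries per group was not tested. For each list, members were also counted with p-values adjusted over the list alone. Counts of members with an unadjusted p under 0.05 are to be set against all tested genes, where 1975 of 11419 had one.

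The rule for named genes was also fixed then. It takes the 12 largest rises and the 12 largest falls among called genes with a mean of at least 2 CPM whose groups did not overlap, predicted gene models left out. It adds up to 4 members of each described list, called members first and then those with the smallest p. It also takes, whatever their values, Nr4a1, Crem, Per1, Sik1, Pde4b, Pde4d, adrenergic receptor genes, Scgb1a1, Scgb3a2, Cyp2f2, Gdf15, Fgf21, Il6, Metrnl, Bmp8b, Actb and Gapdh. Some genes of the rule are not described. Genes named outside this rule are marked as chosen after their values were seen.

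The procedure was tested on simulated counts drawn from the means and library sizes of these 4 libraries for 11333 genes, with 50 genes changed at each of 4 folds. At a fold of 1.25 it called 22% of the changed genes, at 1.5 it called 76%, at 2 it called 96% and at 4 it called 100%. Of 155 genes called, 8 (5.16%) were false. Simulated genes varied independently and lacked the trend on transcript length described below. That share is thus not the error rate of the genes called in the real data.

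Alternatives fixed before the data were examined were DESeq2 size factors or total counts as scaling, and no filter or a stricter filter (at least 10 counts in every library of a group and a mean of 1 CPM). Others were the DESeq2 1.42.0 Wald test, limma voom, robust dispersion, and the replicate number as a block. Further ones were the 20 most abundant genes left out, a fold threshold (log2 0.5, glmTreat), each library left out in turn, and an estimated correlation or fry for lists. Added after seeing the data were the removal of each library's trend (lowess, span 0.3) on transcript length or on GC content, and the summing of counts of genes whose exons overlap. Length, GC content and exon overlap came from GENCODE M21, an annotation of another build (GRCm38), through gene identifiers (21973 of 22063 found) and bedtools 2.31.1. No coordinates are printed because that build is not the one behind the counts. Figures were drawn with matplotlib 3.10.9.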

Results

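Gene expression was measured by RNA sequencing in C22 cells, an immortalized mouse Club cell line, to ask how airway epithelial cells respond to norepinephrine (NE), the transmitter of sympathetic nerve fibres. The series places this question in the setting of nerve fibres in the lung that contact the epithelium and of heat production by adipose tissue. The 2 NE libraries came from cells given 10 µM NE for 3 h and the 2 vehicle libraries from cells given vehicle for the same time. Total counts were 14820258 and 14783176 in the vehicle libraries and 15657173 and 18491334 in the NE libraries, and between 13422 and 13596 genes had at least 1 count. Between libraries, the chi-square per degree of freedom was 6.69 within vehicle, 4.64 within NE and between 6.30 and 13.9 across groups. No pair thus agreed within sampling noise, as a library deposited 2 times would, and each library was counted separately, which does not show that they are independent. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The groups lay close together. Across genes, the Pearson correlation of log-CPM was 0.991 between the vehicle libraries, 0.992 between the NE libraries and between 0.987 and 0.990 across groups. The first principal component held 46.9% of the variance, with the vehicle libraries at -16.8 and -11.8 and the NE libraries at 9.41 and 19.2. Mitochondrial transcripts took 3.88% and 4.24% of the counts in the vehicle libraries and 3.73% and 3.60% in the NE libraries.

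Among adrenergic receptor genes, Adra1b was the most abundant, with 21.7 ± 8.33 CPM in vehicle and 16.3 ± 1.71 CPM in NE (SD, n = 2 each). Adra1d was found at 0.773 ± 0.618 and 0.780 ± 0.288 CPM. Adra2a had 9 counts over the 4 libraries. Adra1a, Adra2b, Adra2c, Adrb1 and Adrb3 had 0 counts, which allows up to 0.0471 CPM. Neither Adra1b nor Adra1d was called in edgeR. Their log2 fold changes were -0.41 ± 0.19 (SE) for Adra1b (adjusted p = 0.269) and 0.03 ± 0.62 for Adra1d (adjusted p = 0.988). The list of adrenergic receptors and desensitisation also holds the arrestin gene Arrb1 (log2 fold change -0.17 ± 0.08, adjusted p = 0.301) and the receptor kinase gene Grk2 (-0.05 ± 0.07, adjusted p = 0.766). Among its 10 tested genes 0 were called by edgeR, DESeq2 or limma voom and 1 had an unadjusted p under 0.05. That list as a whole did not stand apart (camera adjusted p = 0.65). Of the genes for catecholamine uptake and breakdown, 4 of 12 could be tested and 0 were called by any of the 3 tools, with 0 at an unadjusted p under 0.05. The breakdown enzyme gene Maoa (309.5 ± 60.3 CPM in vehicle, 304.4 ± 14.7 in NE) was among them, and the transporter gene Slc6a2 (chosen after its values were seen) had 0 counts. Adra1b depended on the vehicle libraries, which held 27.6 and 15.8 CPM: its log2 fold change was 0.05 without the first of them and -0.75 (adjusted p = 1.20e-05) without the second.

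The cells carried few transcripts of mature Club cells. The secretoglobin gene Scgb1a1, the classical Club cell product, had 2 counts over the 4 libraries, and Scgb3a2 and the cytochrome P450 gene Cyp2f2 had 0. Of 32 Club cell markers, 8 could be tested, 5 had a mean of at least 10 CPM and 16 had 0 counts. Among those present were Aldh1a1 (862.7 ± 135 CPM in vehicle and 780.3 ± 11.7 in NE) and Ephx1 (150.3 ± 7.83 and 134.8 ± 3.79). Krt8, a keratin of simple epithelia, was found at 874.3 ± 29.9 and 926 ± 34.8 CPM, whereas the epithelial adhesion gene Epcam had 0 counts and Cdh1 had 18 in all. Vim, the mesenchymal filament gene, was found at 2914 ± 323 and 2714 ± 32.8 CPM and the collagen gene Col1a1 at 1276 ± 127 and 1125 ± 3.92 CPM. Epcam, Cdh1 and Vim were chosen after their values were seen. At least 10 CPM was reached by 17 of 27 fibroblast and mesenchymal markers, 7 of 14 alveolar type 1 markers, 4 of 13 basal cell markers, 4 of 16 alveolar type 2 markers and 6 of 28 epithelial and keratin genes. For goblet, ciliated, neuroendocrine and tuft, endothelial and leukocyte markers it was 1 gene each, of 14, 21, 22, 16 and 24 respectively. No marker gene of these 11 lists was called between NE and vehicle by edgeR, DESeq2 or limma voom. An unadjusted edgeR p under 0.05 was found for 7 of 20 tested mesenchymal markers, 2 of 11 alveolar type 1 markers, 2 of 11 epithelial genes, 2 of 5 basal markers and 1 of 8 Club cell markers. It was found for 1 gene each among alveolar type 2, neuroendocrine and tuft, endothelial and leukocyte markers. Neither goblet nor ciliated markers gave any (0 of 1 and 0 of 2). Over all tested genes it was found for 1975 of 11419. The camera adjusted p was 0.295 for mesenchymal, 0.321 for alveolar type 1, 0.392 for basal, 0.431 for epithelial and 0.526 for Club cell markers. The other lists had fewer than 5 tested members.

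After 3 h of NE, 39 genes were higher and 140 lower of 11419 tested, 1.57% of the genes, most by small amounts. The median log2 fold change was 0.36 among the higher genes and -0.53 among the lower ones. Only 3 higher and 14 lower genes passed an absolute log2 fold change of 1. The largest rise under the naming rule was that of Nnt, which encodes the mitochondrial nicotinamide nucleotide transhydrogenase (ENSMUSG00000025453; 12.3 ± 2.36 to 32.8 ± 7.49 CPM, log2 fold change 1.42 ± 0.16 SE, adjusted p = 5.05e-04). Next came the ATP synthase subunit gene Atp5mpl (0.58 ± 0.12, adjusted p = 0.0329) and the complex I subunit gene mt-Nd3 (0.49 ± 0.07, adjusted p = 0.00385). The second identifier that carries the symbol Nnt (ENSMUSG00000116207, chosen after its values were seen) fell, with a log2 fold change of -0.76 ± 0.11 (adjusted p = 0.00265). The counts summed over both gave -0.03 ± 0.08 (adjusted p = 0.908), so a change of Nnt itself is not shown. The other 9 rises had log2 fold changes between 0.38 and 0.48 and adjusted p-values between 0.0261 and 0.0446. They were Med6, a Mediator subunit, Pdcd10, Avpi1, Plac8, Rps21 and Rpl38, which encode ribosomal proteins, the interferon-inducible gene Ifi211, the focal adhesion gene Parvb and Gcsh, of the glycine cleavage system. Plac8, the most abundant of them, went from 463.3 ± 72.0 to 615.0 ± 0.006 CPM. Zfp967 and the predicted gene Gm27029 also passed an absolute log2 fold change of 1 among the higher genes (1.73 ± 0.41 and 2.07 ± 0.43; chosen after their values were seen), at levels near 3 CPM in NE.

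Falls of genes at higher levels included Gabre, a subunit gene of the GABA-A receptor (ENSMUSG00000031340; 27.5 ± 0.167 to 12.9 ± 2.50 CPM, log2 fold change -1.10 ± 0.13, edgeR adjusted p = 0.00127). Others were Ahnak2, which encodes a very large scaffold protein (ENSMUSG00000118667; 141.9 ± 5.59 to 75.9 ± 22.7 CPM, -0.91 ± 0.13, adjusted p = 0.00257), and the immediate-early transcription factor gene Egr1 (ENSMUSG00000038418; 61.6 ± 21.8 to 32.2 ± 9.29 CPM, -0.94 ± 0.19, adjusted p = 0.0275). The autophagy gene Atg9b fell by 1.36 on the log2 scale (SE 0.18, adjusted p = 0.00244) and the pseudokinase gene Nrbp2 by 0.94 (SE 0.17, adjusted p = 0.0148). Further falls were those of Sycp1, a gene of the meiotic synaptonemal complex, the collagen gene Col9a3, the sodium-proton exchanger gene Slc9a5, Il18bp, which encodes a binding protein of interleukin-18, Lime1 and the ESCRT gene Chmp4c. These had log2 fold changes between -1.68 and -0.90 at vehicle means of at most 9.51 CPM, with adjusted p-values between 0.0312 and 0.0440. Commd1b had the largest fall under the rule (-2.72 ± 0.58, adjusted p = 0.0329), from counts of 159 and 156 to 53 and 0. Its exons overlap those of Commd1 and B3gnt2. Exons also overlap those of another gene for Atg9b, Col9a3, Il18bp, Lime1 and Chmp4c, so their values are uncertain. The same holds for both Nnt identifiers, Gapdh, Gm27029, Gm20605, Gm20390 and Pcdhgc4, and for Ccne2, Col4a1, Cox6c, Manf, Hspe1 and mt-Nd5, which are described below. Of the 12 falls under the rule DESeq2 also called 1, Gabre, and limma voom 12. Of the 12 rises DESeq2 called 6 and limma voom 12. DESeq2 gave no adjusted p for 3764 of the 11419 genes by its own filtering. Genes without one cannot be called by DESeq2, here or in the counts for lists. The control genes Actb (log2 fold change -0.08 ± 0.08, adjusted p = 0.644) and Gapdh (0.06 ± 0.07, adjusted p = 0.722) were not called.

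**Figure D1:**
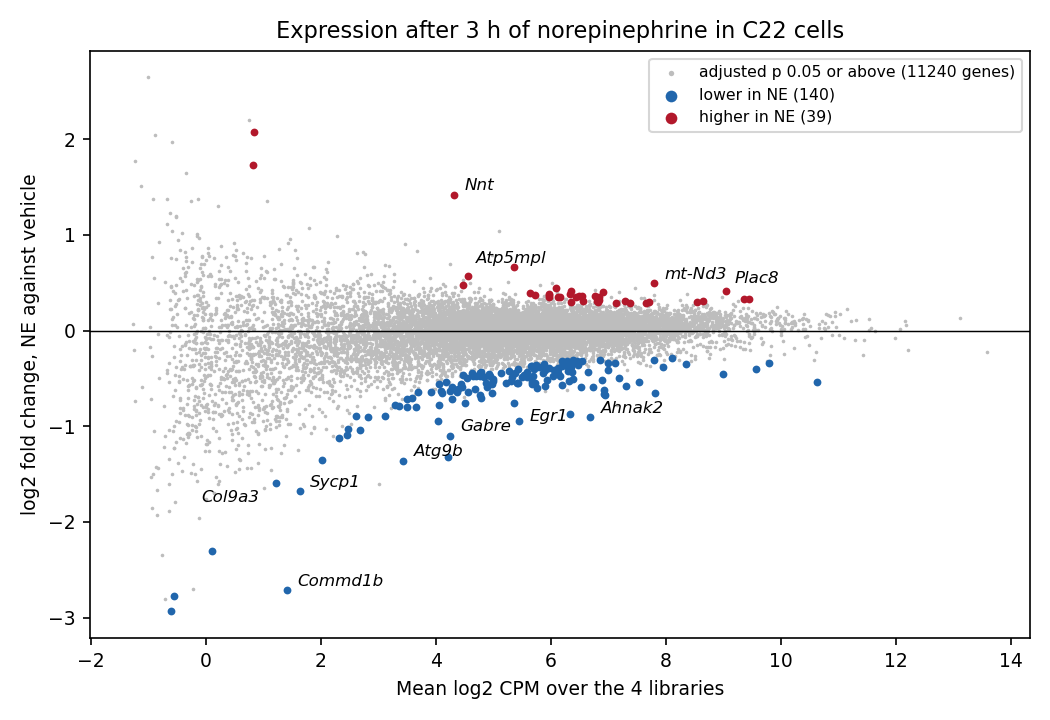
Each point is 1 of the 11419 tested genes, with the mean log2 CPM over the 4 libraries on the x axis and the log2 fold change of NE against vehicle on the y axis; red points are the 39 genes called higher and blue points the 140 called lower (edgeR, adjusted p under 0.05), and genes of the naming rule are labelled. Most calls lie within a log2 fold change of 1 of no change.

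In all 179 called genes the groups did not overlap, against 49.2% of all tested genes and 33.3% by chance with 2 against 2 libraries. The count of calls rested on single libraries, with the lone library of a group then assumed to vary like the other group. Without the first vehicle library 121 genes were higher and 310 lower, and without the second vehicle library 312 and 428. Without the first NE library it was 4 and 68. Without the second, deepest NE library it was 2 and 2, and 0 of the 24 genes that the naming rule takes for their change were then called. The 4 higher genes were Nnt, Pdcd10, Zfp968 and Gm4724. The 2 higher genes of the last set were Gm20390 and Rps29 and the 2 lower ones Gm20605 and Pcdhgc4, and all of these but Nnt and Pdcd10 were chosen after their values were seen. DESeq2 called 24 higher and 51 lower, of which 65 were shared with edgeR. With total counts as scaling the split was 12 higher and 120 lower (9.09% higher, against 21.8%). Against a log2 threshold of 0.5, 1 gene was higher, the first Nnt identifier, and 1 lower, Gm20605.

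Genes of protein synthesis and respiration were slightly higher in NE as groups by camera with the preset correlation, but not with an estimated one. Of the 48 cytosolic ribosomal protein genes of the list, which leaves out others, 48 had a positive log2 fold change (median 0.16). Among them 2 rose, Rpl38 (0.38 ± 0.09, edgeR adjusted p = 0.0431) and Rpl30 (0.29 ± 0.07, adjusted p = 0.0431), and 16 passed when adjusted over the list alone. DESeq2 called 2 of the list, with Rpl30 but without Rpl38, and limma voom 2. Of 32 further genes with ribosomal protein symbols, found outside the list, 32 were positive and 4 rose in edgeR, Rpl41, Rpl35, Rps21 and Rps27. DESeq2 also called 4 of the 32, with another gene in place of Rps27, and limma voom called 5. Of the 33 nuclear genes of oxidative phosphorylation in the list, 31 were positive (median 0.15), 0 passed by edgeR, DESeq2 or limma voom, 12 had an unadjusted p under 0.05 and 6 passed when adjusted over the list alone. Among these were the cytochrome oxidase gene Cox6c (0.28 ± 0.07, adjusted p = 0.0622 over all genes) and the complex I gene Ndufv2 (0.25 ± 0.07, adjusted p = 0.0976). Of 46 further nuclear genes of oxidative phosphorylation, found by symbol outside the list, 45 were positive and 3 rose in edgeR, Atp5mpl, Atp5g3 and Cox7b (0 calls in DESeq2, 3 in limma voom). Both searches by symbol were made after the values were seen, and Rpl41, Rpl35, Rps27, Atp5g3 and Cox7b were chosen then. Of 36 genes of ribosome biogenesis, 34 were positive (median 0.10), 0 passed by any of the 3 tools or when adjusted over the list alone and 7 had an unadjusted p under 0.05. Nip7 stood at 0.27 ± 0.07 (adjusted p = 0.0700) and the nucleolar gene Npm1 at 0.17 ± 0.07 (adjusted p = 0.204). With the preset correlation, camera gave adjusted p-values of 1.47e-10 for ribosomal proteins, 2.92e-07 for oxidative phosphorylation and 5.87e-04 for ribosome biogenesis. None of the 3 held with an estimated correlation, where each had an adjusted p = 0.764. With that setting 0 of the 35 lists passed, so the loss does not set these 3 apart from other lists. Ribosomal protein genes have many near-identical processed copies in the genome, so their single values are uncertain.

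Fold changes also fell with transcript length over all genes. The median log2 fold change was 0.11 in the tenth of genes with the shortest transcripts and -0.09 in the tenth with the longest. Across 11399 genes, which are not independent replicates, Spearman's rho between log2 fold change and length was -0.27. The slope of log-CPM per doubling of length was 0.03 in both vehicle libraries, -0.01 in the first NE library and -0.05 in the second. The median transcript length was 1443 nt for genes called higher and 4472.5 nt for genes called lower, against 3470 nt for all genes. It was 1139.5 nt for the ribosomal protein genes and 1661 nt for those of oxidative phosphorylation. With each library's length trend removed, 13 genes were higher and 59 lower, and 11 of the 24 genes that the naming rule takes for their change were still called. Ahnak2, which is among the 24, had no known transcript length and was not tested in that setting.

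**Figure D2:**
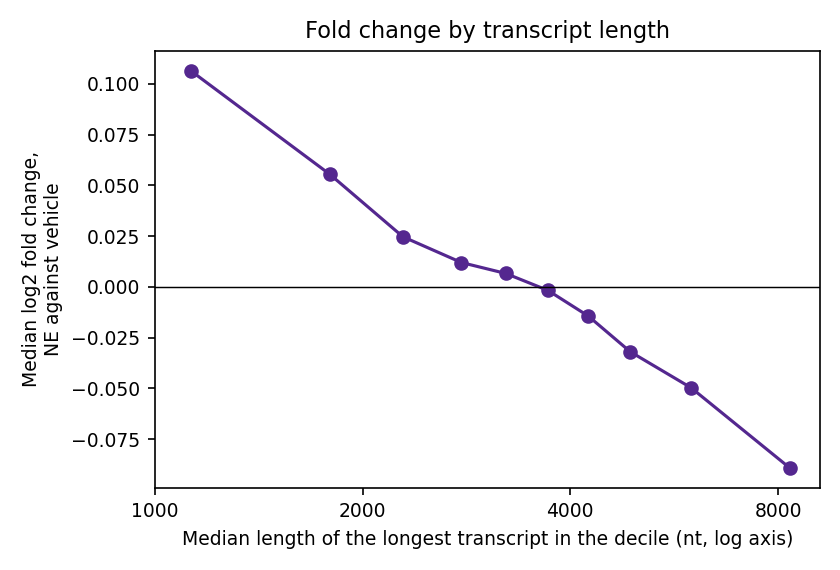
Median log2 fold change of NE against vehicle (y axis) in 10 bins of tested genes ordered by the length of the longest transcript in nucleotides (x axis, log scale). The medians go from 0.11 in the bin of shortest transcripts to -0.09 in the bin of longest ones.

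Targets of p53 and genes of the Notch pathway were lower in NE as groups by camera with the preset correlation, but not with an estimated one. Of 22 p53 targets, 20 had a negative log2 fold change (median -0.15) and 7 passed when adjusted over the list alone. The target that fell was the desmosome-linked apoptosis gene Perp (29.2 ± 1.5 to 21.03 ± 0.615 CPM, -0.48 ± 0.11, edgeR adjusted p = 0.0408), and 21 did not pass; DESeq2 called 0 of the 22 and limma voom 1. Trp53inp1 stood at -0.34 ± 0.09 (adjusted p = 0.0594) and Mdm2, the ubiquitin ligase of p53, at -0.26 ± 0.07 (adjusted p = 0.0698). Of 8 tested Notch genes 7 were negative (median -0.34), edgeR and DESeq2 called 0, limma voom called 1, 3 had an unadjusted p under 0.05 and 2 passed when adjusted over the list alone. The receptor gene Notch1 stood at -0.59 ± 0.15 (adjusted p = 0.0516) and the ligand gene Jag1 at -0.31 ± 0.12 (adjusted p = 0.195). With an estimated correlation camera gave an adjusted p = 0.764 for both lists, but 0 of the 35 lists passed in that setting. With the preset correlation camera gave adjusted p-values of 0.00272 for p53 targets and 0.0459 for Notch. Without the first vehicle library these became 0.158 and 0.296, and without the second NE library 0.233 and 0.142. The Notch call was also lost with total counts as scaling (adjusted p = 0.0742) and with no low-count filter (adjusted p = 0.217). Removal of the GC trend lost it too (adjusted p = 0.0617). With fry neither the p53 nor the Notch list was called (adjusted p = 0.409 for both).

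The genes that cAMP and CREB, the pathway below beta-adrenergic receptors, are known to induce did not move together. Of 22 tested genes of this list, 0 passed by edgeR, DESeq2 or limma voom or when adjusted over the list alone. Of these genes 8 had an unadjusted p under 0.05, and 8 were positive and 14 negative (median -0.15, camera adjusted p = 0.321). Over all tested genes, 1975 of 11419 had an unadjusted edgeR p under 0.05. Nr4a1 stood at 11.3 ± 9.11 CPM in vehicle and 16.1 ± 1.11 in NE (log2 fold change 0.51 ± 0.32, 95% interval -0.17 to 1.20, adjusted p = 0.437). Its counts in the vehicle libraries were 72 and 264, and its log2 fold change was -0.14 without the first of them and 1.74 (adjusted p = 1.19e-12) without the second. Crem (-0.13 ± 0.21, interval -0.56 to 0.30), Sik1 (-0.25 ± 0.09, interval -0.45 to -0.06), Per1 (-0.20 ± 0.08, interval -0.37 to -0.02), Pde4b (0.09 ± 0.14, interval -0.19 to 0.38) and Pde4d (0.50 ± 0.23, interval 0.02 to 0.97) had adjusted p-values between 0.166 and 0.795. Fos stood at -0.80 ± 0.27 (adjusted p = 0.137) and the phosphodiesterase gene Pde4a at -0.46 ± 0.14 (adjusted p = 0.104). The 95% interval excluded a rise of 2-fold for 20 of the 22 genes and of 1.5-fold for 15. These values hold for 3 h, the only time sampled, so an earlier rise that had ended by then would not be seen. The list's direction turned without the second vehicle library (adjusted p = 0.411) and without the second NE library (adjusted p = 0.999). In the list of cAMP and calcium signalling machinery, 0 of 23 genes passed by any of the 3 tools, 5 had an unadjusted p under 0.05, and the camera adjusted p was 0.619. When adjusted over the list alone 1 passed, the CREB coactivator gene Crtc2 (-0.34 ± 0.09, adjusted p = 0.0739 over all genes).

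Immediate-early genes of the serum response included 2 of the called falls at 3 h, the only time sampled. Egr1 fell as above, and Ccn2, a secreted matricellular protein gene, went from 73.5 ± 16.9 to 49.2 ± 7.5 CPM (-0.58 ± 0.13, edgeR adjusted p = 0.0368). Of the 22 tested genes 17 were negative, 20 did not pass over all genes, DESeq2 called 0 and limma voom 2, and robust dispersion lost both falls. Of the list 4 passed when adjusted over the list alone (camera adjusted p = 0.295). Ccn1 stood at -0.62 ± 0.18 (adjusted p = 0.0833) and Btg2 at -0.42 ± 0.12 (adjusted p = 0.0929). Among 13 genes of ERK feedback, 1 rose, the phosphatase gene Dusp4 (102.7 ± 6.61 to 128.4 ± 5.57 CPM, 0.32 ± 0.07, adjusted p = 0.0431), and 10 were positive; DESeq2 called 0 and limma voom 1. Etv5 stood at 0.41 ± 0.15 (adjusted p = 0.161). That list had a camera adjusted p of 0.321. Of 21 tested YAP and TEAD targets, 2 fell, Ccn2 and the ankyrin repeat gene Ankrd1 (35.2 ± 0.221 to 25.8 ± 2.28 CPM, -0.45 ± 0.10, adjusted p = 0.0431). DESeq2 called 1 of the list, neither of these, and limma voom 4. When adjusted over the list alone 6 passed (camera adjusted p = 0.0966).

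**Figure D3:**
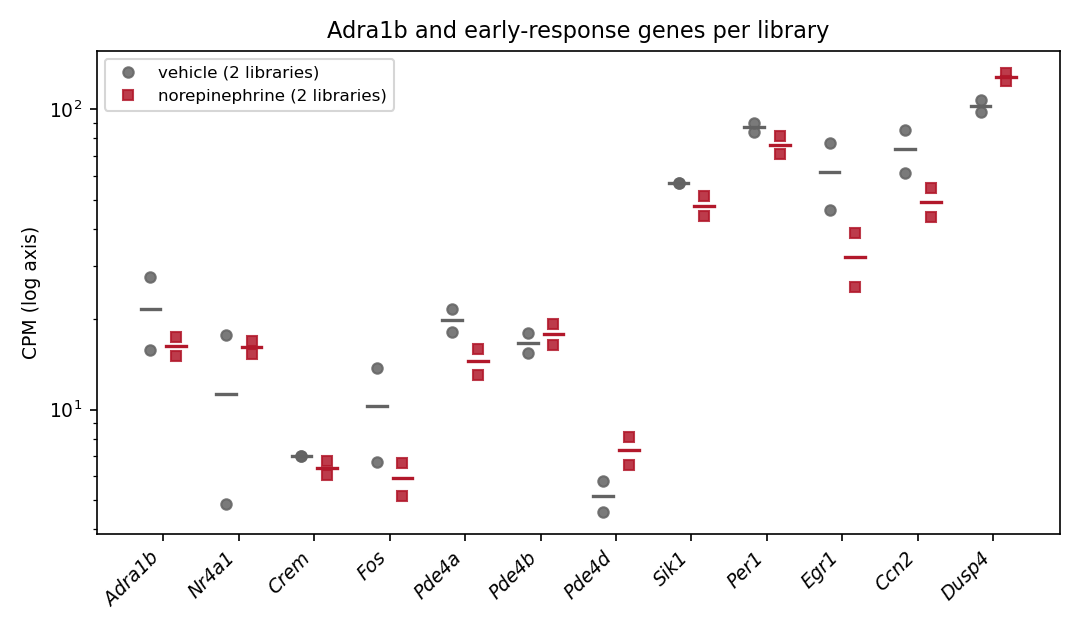
CPM on a log axis (y) of Adra1b and early-response genes (x) in each library; grey circles are the 2 vehicle libraries, red squares the 2 NE libraries, and short lines the group means. The groups do not overlap for Egr1, Ccn2 and Dusp4, which were called, nor for Crem, Fos, Pde4a, Pde4d, Sik1 and Per1, which were not. For Nr4a1 the vehicle libraries lie at 4.84 and 17.7 CPM on either side of the NE libraries.

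Secreted factors that are linked with adipose thermogenesis were examined because the series concerns heat production by fat. Of 44 such genes 24 could be tested, and 0 passed by edgeR, DESeq2 or limma voom or when adjusted over the list alone. An unadjusted p under 0.05 was found for 5 (median log2 fold change -0.08, camera adjusted p = 0.431). Metrnl, which encodes a hormone that acts on fat, stood at 41.7 ± 7.59 and 34.5 ± 0.794 CPM (-0.27 ± 0.11, interval -0.51 to -0.03, adjusted p = 0.226). Nampt (0.23 ± 0.07, adjusted p = 0.0998), the cytokine gene Lif (-0.46 ± 0.15, adjusted p = 0.119) and Nrg1 (-0.56 ± 0.19, adjusted p = 0.142) had the smallest p-values. Gdf15 stood at 0.907 ± 0.238 and 0.717 ± 0.164 CPM (-0.35 ± 0.54, adjusted p = 0.787) and Il6 at 1.38 ± 1.09 and 1.32 ± 0.857 CPM (-0.10 ± 0.57, adjusted p = 0.952). At these levels the depth is limiting, and the 95% intervals of both genes include a 2-fold fall. Fgf21 had 4 counts in all and Bmp8b 0. The interval excluded a rise of 2-fold for 22 of the 24 tested genes.

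The lists of inflammatory and interferon genes held 3 of the called falls. Nfkbiz, which encodes a nuclear regulator of NF-kB, went from 51.4 ± 1.90 to 35.4 ± 6.61 CPM (-0.54 ± 0.11, edgeR adjusted p = 0.0312), 1 of 18 tested genes of NF-kB and inflammatory cytokines. Of the 18, 13 were negative and 4 passed when adjusted over the list alone (camera adjusted p = 0.0966), among them the cytokine gene Csf1 (-0.42 ± 0.11, adjusted p = 0.0572 over all genes). Of 35 interferon response genes, 2 fell, Oas2 (194.1 ± 31.5 to 129.6 ± 21.6 CPM, -0.58 ± 0.11, adjusted p = 0.0167) and Rsad2 (-0.61 ± 0.14, adjusted p = 0.0431), both antiviral effectors. The other 33 did not pass. DESeq2 called 0 of the 35 and limma voom 2, and robust dispersion lost Oas2. Of all 35, 24 were negative (camera adjusted p = 0.295). Neither the 15 glucocorticoid response genes nor the 16 circadian clock genes gave a call by any of the 3 tools (6 and 3 at an unadjusted p under 0.05; camera adjusted p = 0.327 and 0.933). Errfi1 stood at 0.40 ± 0.15 (adjusted p = 0.168) and the clock gene Per3 at -0.86 ± 0.23 (adjusted p = 0.0650), which passed when adjusted over the list alone. Of 10 genes of airway ion and fluid transport 0 passed by any of the 3 tools and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.961), the water channel gene Aqp5 at 0.28 ± 0.10 (adjusted p = 0.146).

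Among proliferation genes, the cyclin gene Ccne2 rose, from 82.6 ± 5.25 to 105.8 ± 5.94 CPM (0.36 ± 0.08, edgeR adjusted p = 0.0354). The call was lost when overlapping genes were summed (0.25, adjusted p = 0.0698). Ccne2 was the 1 call of 29 S phase genes, of which 22 were positive (camera adjusted p = 0.13). Of 34 genes of G2 and mitosis, edgeR and limma voom called 0 and DESeq2 1, 9 had an unadjusted p under 0.05 and 24 were positive (camera adjusted p = 0.13). The proliferation marker gene Mki67 stood at -0.25 ± 0.07 (adjusted p = 0.0741) and Cdk1 at 0.21 ± 0.07 (adjusted p = 0.137). Of 20 TGF-beta response genes, 1 fell, the basement membrane collagen gene Col4a1 (999 ± 66.1 to 791.7 ± 42.2 CPM, -0.34 ± 0.07, adjusted p = 0.0342), and the camera adjusted p was 0.282. Thbs1 stood at -0.36 ± 0.11 (adjusted p = 0.0888). Of 25 genes of extracellular matrix and proteases 0 passed by any of the 3 tools and 5 had an unadjusted p under 0.05, with the protease gene Mmp3 at 0.44 ± 0.12 (adjusted p = 0.0691; camera adjusted p = 0.774). For 7 Wnt response genes these numbers were 0 and 3 (camera adjusted p = 0.392), and for 19 apoptosis regulators 0 and 3 (camera adjusted p = 0.675). By fry's mixed test, which asks whether members change in either direction, the matrix list (adjusted p = 0.0114), the apoptosis list (0.0311) and the mitochondrial list (0.0389) passed. By its directional test no list passed.

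The 13 protein-coding genes of the mitochondrial genome moved apart. Besides mt-Nd3, which rose, 12 did not pass over all genes, while DESeq2 called 3 and limma voom 1. Adjusted over the list alone 2 were higher and 6 lower, among them mt-Nd5 (-0.31 ± 0.08, edgeR adjusted p = 0.0698 over all genes) and mt-Nd2 (-0.23 ± 0.07, adjusted p = 0.0905), and the camera adjusted p was 0.398. In the remaining lists of metabolism and stress no gene was called by edgeR or DESeq2. These were glycolysis and hypoxia (28 genes, 4 at an unadjusted p under 0.05, camera adjusted p = 0.117), heat shock (15, 3 and 0.0966), the unfolded protein response and ATF4 (30, 7 and 0.327), NRF2 and oxidative stress (27, 7 and 0.76), fatty acid synthesis and lipid storage (23, 5 and 0.321) and cholesterol biosynthesis (24, 4 and 0.933). Limma voom called 1 gene of cholesterol biosynthesis and 0 of the others. In the first 5 of these lists, the members with the smallest p were the hypoxia gene Bnip3 (0.39 ± 0.11, adjusted p = 0.0929), the chaperonin gene Hspe1 (0.19 ± 0.07, adjusted p = 0.168), Manf (0.34 ± 0.11, adjusted p = 0.112), the drug transporter gene Abcc1 (-0.29 ± 0.08, adjusted p = 0.0726) and the desaturase gene Fads2 (-0.20 ± 0.07, adjusted p = 0.134). Median, mean and test differed in sign for NRF2 and oxidative stress (median 0.01, mean -0.003, direction up), for matrix and proteases (median -0.05, mean 0.009, direction down) and for airway transport (median -0.01, mean -0.01, direction up).

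**Figure D4:**
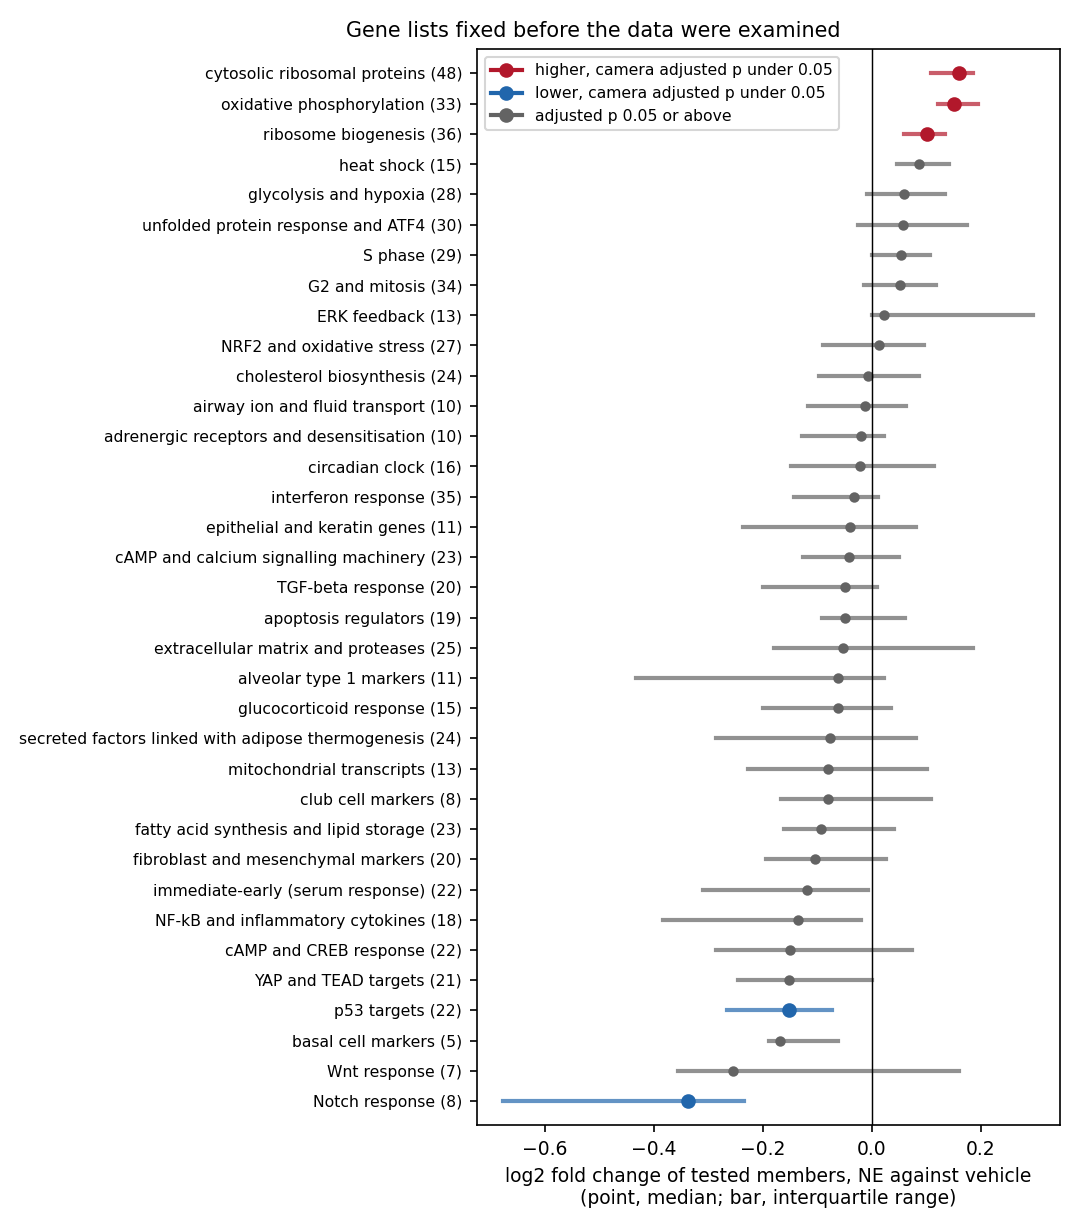
Median (point) and interquartile range (bar) of the log2 fold change of NE against vehicle (x axis) over the tested members of the 35 gene lists (y axis, number of members in brackets). Red and blue mark the 5 lists with a camera adjusted p under 0.05 at the preset correlation, 3 higher and 2 lower. With an estimated correlation each of the 5 had an adjusted p of 0.764, and 0 of the 35 lists passed.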

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

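The removal of length and GC trends and the summing of overlapping genes were chosen after the data were seen. The 179 called genes kept their sign under each alternative that tested them under their own identifier. With 1 library left out this was nearly fixed in advance, as the groups did not overlap in any of these genes. The other alternatives refit the same 4 libraries, so kept signs are no independent support. When overlapping genes were summed, 22 of the called genes went into a sum named after another identifier. The sum then had the opposite sign for 3, Nnt (-0.03), Commd1b (0.06) and Adgre5 (0.08; chosen after its values were seen). The counts of calls moved more. Against 39 higher and 140 lower genes, the counts were 36 and 128 with DESeq2 size factors and 12 and 120 with total counts. They were 84 and 225 with no filter, 43 and 156 with the stricter filter, 50 and 165 with limma voom, 71 and 191 with robust dispersion, and 39 and 139 without the 20 most abundant genes. DESeq2 gave 24 and 51, with 65 genes shared with edgeR and 3764 genes with no adjusted p by its own filtering. The fold threshold gave 1 and 1, the first Nnt identifier and Gm20605, as its construction asks for larger changes. Removing the length trend gave 13 and 59, removing the GC trend 31 and 139, and summing overlapping genes 32 and 104. Leaving out 1 library gave between 2 and 312 higher and between 2 and 428 lower genes; the sets without an NE library were the smallest, and without the second one only 2 of the 179 genes were still called. The cause of the other shifts was not tested. Of the 24 genes that the naming rule takes for their change (mean of at least 2 CPM, predicted gene models left out), 24 were kept with DESeq2 size factors, either filter or limma voom, 17 with total counts and 7 with DESeq2 (6 rises and 1 fall).

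With the replicate number as a block, 84 genes were higher and 236 lower and 7 lists were called. Whether the numbers pair the samples is not known, as the labels do not say so and the deposited columns number the libraries differently. Deviations of same-numbered libraries from their group means had a correlation of -0.0556 across genes, which with 2 libraries per group cannot decide it.

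The 5 called lists were 10 with limma voom and between 3 and 8 with 1 library left out. With an estimated correlation or fry 0 lists were called, and the other alternatives gave between 4 and 7. Robust dispersion, DESeq2 and the fold threshold give no camera value. The cAMP and CREB list turned direction when 1 library was left out (adjusted p between 0.0847 and 0.999) and was never called.

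For the 114 tested gene identifiers named, 1482 of 1776 comparisons with an alternative stayed on the same side of the threshold, and 184 lost and 95 gained a call. Signs turned in 15, none in a gene called with all libraries, where groups that do not overlap nearly fix the sign. Identifiers whose counts went into the sum of another are not among these comparisons. With 1 library left out the log2 fold change ranged from -0.14 to 1.74 for Nr4a1, -0.0184 to 0.204 for Pde4b, -0.755 to 0.0483 for Adra1b and -0.61 to 1.22 for Adra1d. It ranged from -0.94 to 1.08 for Il6, -0.193 to 0.0415 for Actb, -0.21 to 0.19 for Maoa, -0.295 to 0.0245 for Aldh1a1, -0.21 to 0.0153 for Vim and -0.77 to 1.80 for Zfp968. Adra1d also turned to -0.0133 with the length trend removed. The cause was not tested. Depth limits genes near 1 CPM, such as Il6 and Gdf15, whose 95% intervals (-1.49 to 0.79 for Gdf15 and -1.30 to 1.11 for Il6, log2) include a 2-fold fall, and for Il6 a 2-fold rise.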

Other observations

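In this part, the tests of the 2 Nnt identifiers and of the mitochondrial transcripts, the removal of length and GC trends and the summing of overlapping genes were chosen after the results were seen. The list of intron-retaining transcripts was written after some of its members had been noticed among the called genes, and those 7 members were kept out of its test.

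Some transcripts of a class that tends to keep introns and stay in the nucleus, many of them from genes of splicing, were lower in NE. That the class as a whole was lower held only in part, and was lost with an estimated correlation (camera p = 0.294) and without the second vehicle library (p = 0.132). Noticed first were Leng8 (log2 fold change -0.87 ± 0.14 SE, edgeR adjusted p = 0.00538), the p53 regulator gene Mdm4 (-0.67 ± 0.09, adjusted p = 0.00257), Nktr (-0.59 ± 0.11, adjusted p = 0.0148). With them were the cyclin gene Ccnl2 (-0.57 ± 0.09, adjusted p = 0.00385), Ttc14 (-0.50 ± 0.08, adjusted p = 0.00385), Pnisr (-0.47 ± 0.08, adjusted p = 0.0104) and Prpf39 (-0.41 ± 0.08, adjusted p = 0.0261). Of 44 further members, 32 were negative (median -0.08) and 3 fell, the splicing scaffold gene Srrm2 (-0.45 ± 0.09, adjusted p = 0.0284), Rsrp1 (-0.37 ± 0.09, adjusted p = 0.0431) and Tia1 (-0.32 ± 0.07, adjusted p = 0.0431). All of these genes were chosen after their values were seen. Exons of Leng8, Ttc14, Prpf39, Srrm2 and Tia1 overlap those of another gene, so their values are uncertain, and with overlapping genes summed neither Tia1 (-0.28, adjusted p = 0.0550) nor the sum that holds Prpf39 (-0.10, adjusted p = 0.460) was called.

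The hypothesis that this class moves as a whole was tested on the 44 further members, which were lower than other genes (camera p = 0.00245 with the preset correlation). They were measured in the same libraries as the members that prompted the list, and 3 of them were called. The test is thus no independent support. The test passed without the first vehicle library, the first NE library or the second NE library, but not in the 2 settings given above. With the preset correlation, camera gave p = 0.0123 after removal of the length trend and p = 0.000219 after removal of the GC trend. These are model values from 2 libraries per group, where no reordering of libraries could pass. At the preset correlation the members thus stayed lower after each correction. For GC content this argues against that trend as the whole cause. Length was that of the longest annotated transcript, so the length removal may be incomplete and cannot exclude length as the whole cause. Part of the shift went with length. With that trend removed the median was -0.05 (-0.08 before), 28 members were negative (32 before) and 1 was called lower (3 before). With the GC trend removed the median was -0.09, 32 members were negative and 5 were called lower. A nuclear RNA share that differs between the libraries, from extraction or from lysis, and an effect of NE on splicing or decay both stay open, as gene counts do not separate intron from exon reads, and neither was tested.

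Ribosomal protein and oxidative phosphorylation genes were higher in NE, and short transcripts in general were too. With the length trend of each library, fitted without both lists, removed, the medians dropped from 0.16 to 0.07 and from 0.15 to 0.07, and the larger of the 2 camera adjusted p-values was 0.00605. With the GC trend removed it was 2.23e-07 and the medians were 0.18 and 0.17. At the preset correlation both lists thus stayed higher after each removal. This argues against the GC trend as the whole cause, while more than 50% of the median shift went with length. Length was that of the longest annotated transcript, which need not be the one expressed. The length removal may thus be incomplete and cannot exclude length as the whole cause. With an estimated correlation neither list was called before (adjusted p = 0.764) or after removal of the length trend (0.729) or the GC trend (0.778), so the shift of the lists as such rests on the preset one. Before any removal the estimated correlation gave 0 calls among the 35 lists. Within the 13 protein-coding mitochondrial genes, whose transcripts are mostly cut from shared precursors, log2 fold change also fell with annotated length (Spearman rho = -0.6923, two-sided permutation p = 0.0107, Pearson r = -0.78, with genes not independent replicates). It went from 0.49 for mt-Nd3 and 0.31 for mt-Atp8 to -0.31 for mt-Nd5, with the short mt-Nd6 at -0.35 as an exception. Exons of mt-Atp8, mt-Nd5 and mt-Nd6 overlap those of another gene. With the length trend of all genes removed, rho was -0.6703 (permutation p = 0.0139), mt-Nd3 stood at 0.29 and mt-Nd5 at -0.35. At the preset correlation the list as a whole was then called lower (camera adjusted p = 0.0133, against 0.398 before and between 0.167 and 0.999 in the other alternatives), but not with an estimated correlation (adjusted p = 0.729, against 0.794 before). The remaining rho argues against the trend shared with all genes as the whole cause. A steeper length trend of the mitochondrial transcripts themselves, from fragment size or RNA integrity, which the tables do not measure, and a response to NE both stay open.

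The largest fold changes lay on gene models that share exons with a neighbour. Of the 17 called genes with an absolute log2 fold change of at least 1, 12 (70.6%) had exons overlapping those of another gene, against 2494 of 11382 other tested genes (21.9%; Fisher's exact test, two-sided, p = 2.51e-05). Among all called genes with an annotation it was 49 of 177 (27.7%; Fisher's exact p = 0.0676). With overlapping genes summed, 9 of the 12 lost their call and 3 kept it, Atg9b, Col9a3 and the sum that holds Gm20605, although a sum is diluted by an abundant partner. For Nnt, the summed counts of both identifiers (1012, 943, 966 and 1227) gave an adjusted p of 0.908, so reads of 1 locus split between identifiers are a candidate explanation of that pair, and a shift between transcript forms stays open.

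The real grouping called 179 genes and the highest of the other splits of the 4 libraries 0, so 1 of 3 splits gave as many; 3 splits are too few for a share under 0.05.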
